A study of Sus scrofa with 18 samples.

How the data were processed

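RNA from the free wall of the right ventricle of 9 pigs of a mixed breed was measured at baseline and after ligation of coronary arteries had led to failure of that ventricle, giving 18 Affymetrix 3' IVT arrays. Per the labels' protocols, total RNA was extracted with Trizol, purified on RNeasy columns and turned into biotin-labelled cRNA with the GeneChip 3' IVT Express kit. This chemistry primes at the poly(A) tail, so partly degraded RNA loses signal from probes far from the 3' end. Labels of 6 pigs (6, 8, 9, 11, 12 and 13) state 120 min of ischemia for the failure sample. Labels of the other 3 pigs (5, 10 and 14) define failure by right atrial pressure and are worded differently. The former are called label set 1 and the latter label set 2.

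The deposited values are log2 intensities per probe set. They ran from 2.08 to 15.2 over the tested probe sets, with array medians between 5.59 and 5.66. Partek is named in the submitters' processing notes with no version. Background correction, normalization and summarization are not given in the sources used here. The distributions were near-identical on all arrays. If the arrays were scaled to each other, a shift of most transcripts in one direction would not be visible. For arrays, the number of animals limits the precision.

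The number of decimals of the deposited values differed between probe sets. On all 18 arrays, 1473 of the 24123 probe sets had at most 2 decimals and the other 22650 had more. Values were used as deposited.

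Control probe sets (188) were left out of the tests and 23935 were tested. The probe table used here names 1 gene for 10099 probe sets and several for 198, and it does not list 13826 probe sets, which are unnamed here. Of the probe sets with 1 gene, 9989 had a gene identifier in a RefSeq gene table of assembly Sscrofa11.1, and 0 symbols changed by this update. No gene was named from a probe set with several. A gene was represented by its probe set with the highest mean over all arrays, which gave 6765 genes, of which 2261 had more than 1 probe set.

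Failure was compared with baseline within each pig with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, pig as a block, two-sided, Benjamini-Hochberg adjustment over all tested probe sets, threshold adjusted p of 0.05). Adjusted p-values given for genes come from this fit. The pairing comes from the labels, which give each pig's number to its 2 samples. After removal of group means, the samples of a pig correlated with r from 0.449 to 0.750, and in 9 of 9 pigs the baseline sample correlated best with the failure sample of the same pig. The difference in response between label sets was tested as an interaction in the same model. The animals are separate pigs, so the p-values set changes against the spread between animals. In limma that spread is drawn toward a value pooled over all probe sets, and the standard errors given are of this kind. With the spread of each probe set alone, in an unmoderated paired test, 0 probe sets passed.

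Before the data were examined, 34 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 measured members (32 lists) were tested with camera, with a preset correlation of 0.01 and with an estimated one. Named genes are those past the threshold with the same direction in at least 8 of 9 pigs, up to 12 per direction. To these come 39 genes chosen beforehand, of which the array names 32, up to 4 members past the threshold of each list and the 5 genes with the smallest p in the interaction. Those without a named probe set in the table used here include FOSB, NR4A1, HSPA1A, HK2, ACTA1 and MYH6. In the heat shock list, the entry for HSPA1A was measured under the older symbol HSP70.2. Genes named outside this rule are said to be so or are list members that passed adjusted over their list alone.

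The fits were tested on simulated data with the real design and spread, in which 200 of 23935 probe sets were changed. Noise was drawn independently for each probe set, whereas members of several lists varied together in the real data. Planting 200 changes also eases the adjusted threshold, since 16 probe sets passed in the real data. The recovered shares are therefore likely too high for the real data. For failure against baseline, 48% of simulated 1.25-fold changes, 96% of 1.5-fold, 98% of 2-fold and 100% of 3-fold changes were recovered, with 10 false calls. For the interaction, 0% of 1.25-fold, 16% of 1.5-fold, 74% of 2-fold and 96% of 3-fold changes were recovered. Alternatives were no block, pig as a random effect, other scalings, filters on dim probe sets, 1 probe set per gene or the mean of all, other variance models, an unmoderated paired test, each pig left out and each label set alone. Rounding of all values to 2 decimals, a covariate for RNA quality and lists of at least 3 members were added after the data had been seen. The covariate was the log2 difference between the 3' and 5' probe sets of GAPDH on each array.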

Results

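Gene expression was measured in the free wall of the right ventricle of 9 pigs, each sampled at baseline and again in failure after ligation of coronary arteries. Each pig served as its own control, with 9 baseline and 9 failure arrays. The comparison asks which transcripts differ between the failing ventricle and the same ventricle before ligation.

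Several transcripts of red blood cells fell in failure. ALAS2, the erythroid enzyme of the first step of haem synthesis, went from a log2 intensity of 8.57 ± 0.79 to 7.30 ± 0.86 (SD, n = 9) and was 2.41-fold lower (log2 change -1.27, SE 0.14, adjusted p = 0.00486). AHSP, a chaperone of alpha globin, was 2.29-fold lower (-1.19, SE 0.18, adjusted p = 0.0205), and HBM, a globin of the alpha cluster, was 1.78-fold lower (-0.83, SE 0.12, adjusted p = 0.0208). All 3 genes were lower in 9 of 9 pigs, although in pig 14 the changes were close to 0 (-0.11 for ALAS2, -0.07 for AHSP and -0.04 for HBM). FAM46C, a poly(A) polymerase, was 1.65-fold lower (adjusted p = 0.0156) and PPP1R16B, a regulatory subunit of protein phosphatase 1, was 1.51-fold lower (adjusted p = 0.0176), both in 9 of 9 pigs.

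A pair of named genes rose. PTPN4, a tyrosine phosphatase, was 2.05-fold higher in failure (log2 change 1.03, SE 0.17, adjusted p = 0.0342) and was higher in 8 of 9 pigs. NEBL, which encodes the Z-disc protein nebulette, was 1.61-fold higher (0.69, SE 0.11, adjusted p = 0.0342) in 9 of 9 pigs. The other PTPN4 probe sets had log2 changes of 0.27 and 0.03, neither past the threshold, and the mean over all 3 did not pass (0.45, adjusted p = 0.103). A second, dimmer FAM46C probe set had a change of 0.01, and the mean of both did not pass (-0.36, adjusted p = 0.0570).

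**Figure D1:**
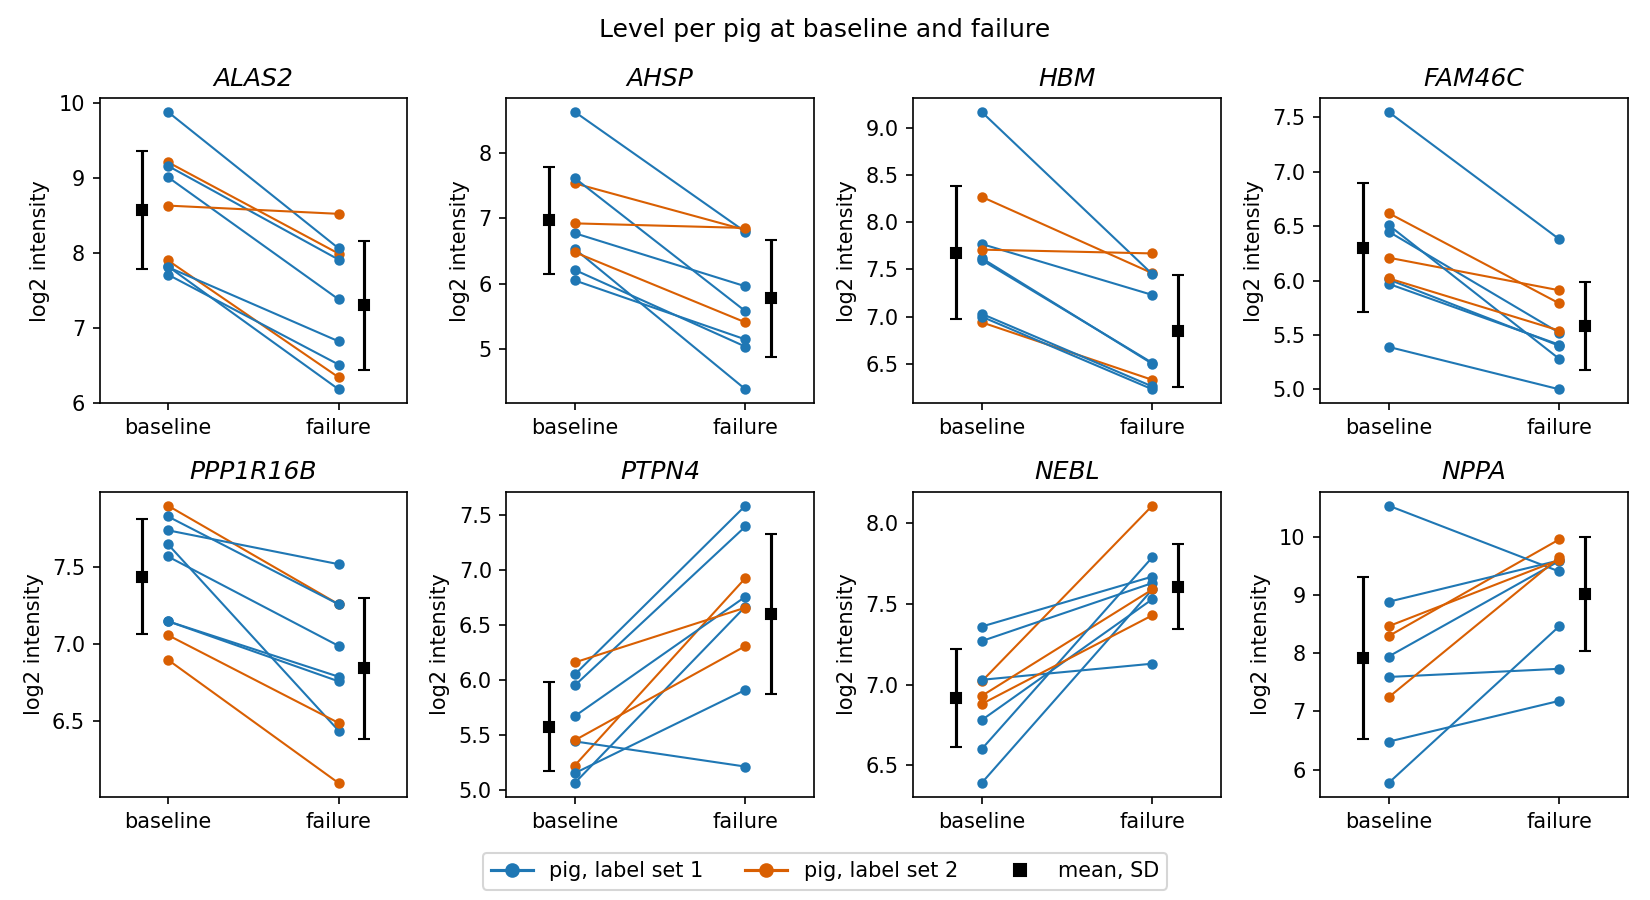
Log2 intensity at baseline and failure of the 7 named genes past the threshold and of NPPA, which did not pass; each line is 1 pig, coloured by label set, and squares with bars give the mean and SD of 9 pigs. ALAS2, AHSP, HBM, FAM46C and PPP1R16B were lower in 9 of 9 pigs, the first 3 of them by 0.11 or less in pig 14.

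In all, 16 of 23935 probe sets passed the threshold in limma, 5 higher and 11 lower, and 5 of these changed at least 2-fold (1 higher, 4 lower). At an unadjusted p under 0.05 there were 1470. With no change at all 1197 are expected, here and for every such count over all tested probe sets. Of the 16 probe sets, 9 carry 1 gene symbol, 2 several and 5 none. Chosen after its values were seen, 1 of 9 B2M probe sets fell by 1.28 on the log2 scale (SE 0.17, adjusted p = 0.0156, lower in 8 of 9 pigs). The other 8 B2M probe sets had a median change of -0.05 (SD 0.11 over probe sets), so this fall is not reported as one of B2M. One of the probe sets of LOC100621559, likewise named after its values were seen, fell by 0.73 (SE 0.10, adjusted p = 0.0158). The other 10 probe sets of this gene had changes from -0.25 to 0.11 and did not pass (adjusted p from 0.357 to 0.996), so this fall is not reported as one of the gene.

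The count depended on the pairing and on single animals. Without the block for pig, 0 probe sets passed (440 at an unadjusted p under 0.05), and an unmoderated paired test also gave 0 (1431 unadjusted). Leaving out pig 5, 9, 10, 11, 12 or 13 gave 9, 3, 2, 4, 4 and 5 probe sets, and leaving out pig 8 gave 26. ALAS2 passed in all 9 of these fits and FAM46C in 8, whereas AHSP and PPP1R16B each passed in 4, and HBM, NEBL and PTPN4 each in 2. The GAPDH 3'/5' difference, a sign of RNA quality, was 0.237 ± 0.556 (SD, n = 9) higher in failure (6 of 9 pigs, exact sign-flip permutation test, two-sided, p = 0.246), and 9 probe sets passed with it as a covariate. ALAS2, FAM46C and PPP1R16B were among these, whereas PTPN4 (0.93, SE 0.18, adjusted p = 0.145), NEBL (0.65, SE 0.12, adjusted p = 0.145), AHSP (-1.20, SE 0.20, adjusted p = 0.0907) and HBM (-0.78, SE 0.14, adjusted p = 0.114) no longer passed. Within label set 1 alone (6 pigs) 3 probe sets passed, and within label set 2 alone (3 pigs) 0 passed, with 1425 and 1211 at an unadjusted p under 0.05.

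Of the 32 measured genes chosen beforehand, 0 passed the threshold in limma. Among immediate early genes, FOS had a log2 change of -0.01 (95% interval -0.62 to 0.59), EGR1 of -0.21 (-0.66 to 0.24), ATF3 of -0.24 (-0.60 to 0.11) and MYC of 0.13 (-0.12 to 0.37). Of the heat shock genes chosen beforehand, HSPB1 lay between -0.22 and 0.22 and DNAJB1 between -0.11 and 0.15. HSP70.2, named outside the rule as the list entry for HSPA1A, had a change of 0.10 (-0.12 to 0.32). The hypoxia target VEGFA had a change of 0.07 (-0.11 to 0.25) at its brightest probe set and of 0.29 (SE 0.12, adjusted p = 0.724), -0.06 and -0.01 at the other 3. ADM had a change of 0.06 (-0.15 to 0.26). PLN, which encodes an inhibitor of the cardiac calcium pump, lay between -0.19 and 0.10 at its brightest probe set. At its other probe set the interval was -0.20 to 0.26. The probe sets of the pump gene ATP2A2 differed: the brightest lay between -0.14 and 0.12, a dim one had a change of -0.04, and the other 2 had changes of 0.22 (SE 0.06) and 0.20 (SE 0.07), with adjusted p of 0.497 and 0.591. The sarcomeric gene MYH7 had a baseline level of 14.96, near the top of the range of the arrays, so its change of -0.01 does not bound a difference.

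Inflammatory genes differed widely between pigs. The IL6 change was 0.64 ± 2.15 (SD, n = 9) and ran from -2.92 in pig 8 to 4.45 in pig 5. CXCL8 ran from -1.50 to 2.93, CCL2 from -1.15 to 3.04 and PTGS2 from -1.50 to 2.47. The extremes of IL6 and CXCL8 rest on dim values: in pig 5 at baseline (3.62 and 2.65) and in pig 8 in failure (3.89 and 3.27) both lay below the 25th percentile of the array (4.02 and 3.91). PTGS2 lay at 3.81 and 3.93 there, so the sizes of these changes are approximate. Each was highest in pig 5, whose arrays also had 3'/5' differences of GAPDH of 2.61 at baseline and 3.55 in failure. None of the 4 passed (adjusted p from 0.864 to 0.919). NPPA, which encodes atrial natriuretic peptide, had a log2 change of 1.11 (SE 0.30, higher in 8 of 9 pigs) with an adjusted p of 0.432. NPPB, the gene of the related B-type peptide, ran from -2.90 in pig 5 to 3.05 in pig 8 (mean 0.31, adjusted p = 0.955). PDK4, an inhibitor of pyruvate oxidation, had a change of 0.22 (SE 0.07, adjusted p = 0.571) at its brightest probe set, higher in 8 pigs and lower in 0. Its other probe set had a change of 0.25 (SE 0.12, adjusted p = 0.804), higher in 7 pigs and lower in 2.

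**Figure D2:**
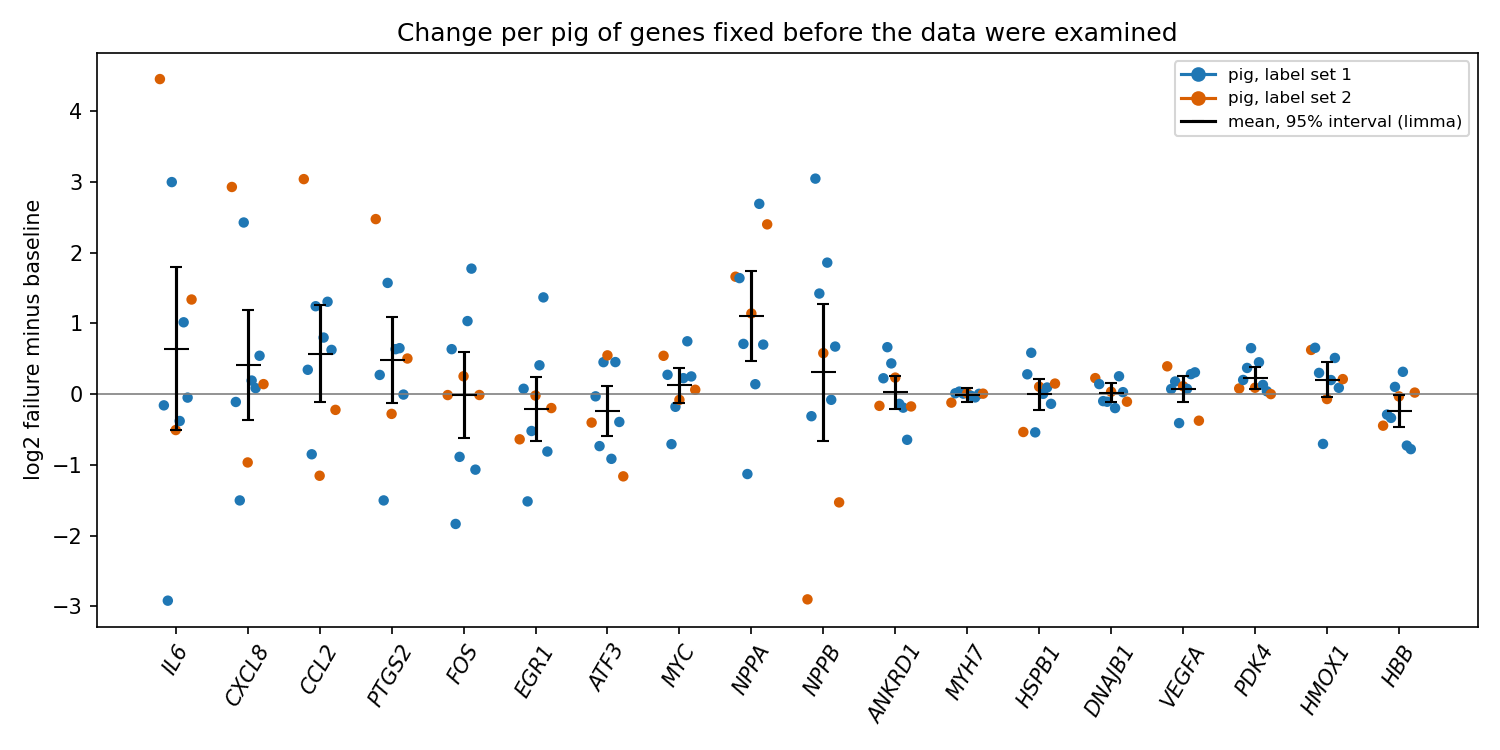
Change per pig (log2 failure minus baseline) of 18 genes chosen before the data were examined; points are pigs coloured by label set, and bars give the mean and the 95% interval from limma. None of these genes passed the adjusted threshold, and IL6 ran from -2.92 to 4.45.

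Among the gene lists, 9 of 32 passed with the preset correlation, 6 toward higher and 3 toward lower values than other genes, and 0 passed with an estimated correlation. Interferon-stimulated genes lay lower in 13 of 13 members (median -0.20, adjusted p = 0.000511; adjusted p = 0.529 with an estimated correlation). None passed over all probe sets, and 0 passed adjusted over the list alone. Glucocorticoid targets lay higher in 9 of 11 members (median 0.16, adjusted p = 0.000619; adjusted p = 0.463 with an estimated correlation). Of these, 0 passed over all probe sets and 1 passed adjusted over the list alone, ANGPTL4 with a change of 0.35 (SE 0.09).

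Genes of coagulation and fibrinolysis lay higher in 8 of 9 members (median 0.15, adjusted p = 0.00721; adjusted p = 0.463 with an estimated correlation) and 0 members past either adjustment. Extracellular matrix genes lay higher in 15 of 18 (median 0.07, adjusted p = 0.0236; adjusted p = 0.529 with an estimated correlation) and 0 past either adjustment. The wall stress list (8 of 9 higher, adjusted p = 0.0384) and the atrial marker list (6 of 6 higher, adjusted p = 0.0384) share NPPA, the 1 member that passed adjusted over each list alone. Their adjusted p values were 0.584 and 0.485 with an estimated correlation. The p53 and growth arrest list had a median of 0.02 with 8 of 13 higher (adjusted p = 0.0458; adjusted p = 0.463 with an estimated correlation) and 0 past either adjustment.

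Oxidative phosphorylation genes lay lower in 23 of 27 members, with a median of -0.05 (adjusted p = 0.0417; adjusted p = 0.724 with an estimated correlation) and 0 members past either adjustment. With the GAPDH 3'/5' difference as a covariate, chosen after the data had been seen, the mean of this list went from -0.05 to 0.000140 (adjusted p = 0.893). With it 3 of the 9 lists passed. Of the 5 others that no longer passed, the p53 list had a mean of 0.08 without and 0.10 with the covariate (adjusted p = 0.0801), coagulation 0.12 and 0.10 (0.0801), atrial markers 0.28 and 0.21 (0.422), glucocorticoid targets 0.12 and 0.06 (0.148) and extracellular matrix 0.09 and 0.05 (0.492), all still above 0. Lymphocyte markers lay lower in 7 of 10 (median -0.08, adjusted p = 0.0152; adjusted p = 0.378 with an estimated correlation). Of these, CD8A (-0.49, SE 0.12) and KLRK1 (-0.36, SE 0.10) passed adjusted over the list alone and 0 over all probe sets. Neutrophil markers (median -0.03, adjusted p = 0.856), monocyte and macrophage markers (median 0.00146, adjusted p = 0.790) and endothelial markers (median 0.01, adjusted p = 0.931) did not pass. The remaining lists had adjusted p values from 0.0607 to 0.996. They included immediate early genes (0.879), heat shock proteins (0.194), of which HSPH1 (-0.26, SE 0.06, lower in 9 of 9 pigs) was the 1 member that passed adjusted over the list alone, hypoxia targets (0.856), glycolysis (0.115) and inflammatory genes (0.0857).

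Red blood cell markers had 4 measured members, under the minimum of 5 set beforehand, and were not part of that test. All 4 passed adjusted over the list alone and were lower, and 2 (ALAS2 and AHSP) passed over all probe sets. HBE1, at a dim mean level of 3.61, had a change of -0.49 (SE 0.09, adjusted p = 0.0975). HBB had a change of -0.24 (SE 0.10, adjusted p = 0.770) and was lower in 6 of 9 pigs and higher in 3.

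**Figure D3:**
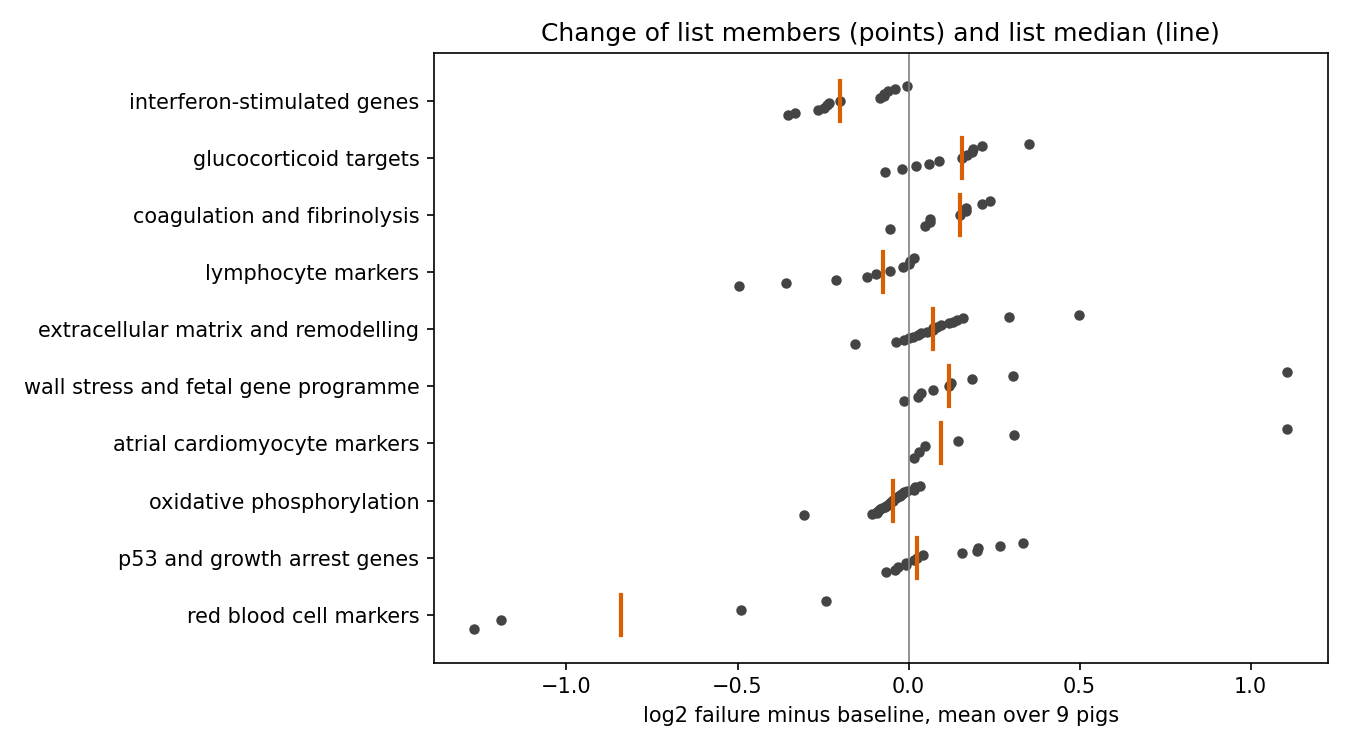
Mean log2 change over 9 pigs of each measured member (points) and the list median (line) for the 9 lists past the threshold with the preset correlation and for the red blood cell markers, which were too few to test. ALAS2 and AHSP lie at -1.27 and -1.19.

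The response was also compared between label sets, 6 pigs against 3. In limma's interaction test 0 probe sets passed, with 1356 at an unadjusted p under 0.05 and a smallest adjusted p of 0.867. The genes with the smallest p were DDX60, CDHR4, GHRL, MMP7 and DDX11. DDX60, an interferon-induced helicase, changed by -0.05 ± 0.22 (SD, n = 6) in label set 1 and by -0.91 ± 0.16 (SD, n = 3) in label set 2, which did not pass (adjusted p = 0.867). Of the other named genes, NPPB had the smallest interaction p. It changed by 1.10 ± 1.27 in label set 1 and by -1.28 ± 1.75 in label set 2 and did not pass (adjusted p = 0.867). AHSP changed by -1.48 ± 0.59 in label set 1 and by -0.62 ± 0.51 in label set 2, also without passing (adjusted p = 0.867). A simulated 1.5-fold difference was recovered for 16% of probe sets, so smaller differences between label sets were not detectable with these numbers of animals.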

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

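The tests of a lower share of blood, of time under anaesthesia and of B2M were chosen after the results were seen. The others were written before their own outcome was known, but not all of them were set before the data were examined. The tests of RNA degradation used the covariate for RNA quality, which was added after the data had been seen. The test of RNA degradation for red blood cell transcripts also included HBM, which is outside the list fixed beforehand and had passed the threshold.

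Single animals stood far from the other 8 of their group in 8 of 129 groups of values, where chance gives about 1 in 20 (6.45). The ALAS2 change was -0.11 in pig 14 and -1.82 to -0.99 in the others. The DDIT3 change was -0.54 in pig 8. In failure, FOS reached 12.98 and S100A9 4.88 in pig 6. MYH7 at baseline was 15.01 in pig 10. PLN was lowest in pig 5 at baseline (12.52) and in failure (12.39), and the baseline array of that pig had a GAPDH 3'/5' difference of 2.61, against 0.61 to 1.49 in the others.

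Red blood cell transcripts were lower in failure, with a median log2 change of -0.83 over HBB, ALAS2, AHSP, HBE1 and HBM. HBM is outside the list fixed beforehand and had passed the threshold, and the median is its own value. HBB changed by -0.24 and was higher in 3 of 9 pigs. The GAPDH 3'/5' difference as a covariate was tied to 184 probe sets. With it the median was -0.78, again that of HBM, and 4 of 5 intervals stayed below 0. ALAS2 (-1.26), AHSP (-1.20) and HBE1 (-0.45) of the list kept theirs below 0, whereas HBB (-0.11, interval -0.27 to 0.06) did not. RNA degradation that differed within pigs is thus argued against as the whole source for the 4 genes with such intervals, but not for HBB. With the covariate AHSP (-1.19, SE 0.18, to -1.20, SE 0.20) and HBM (-0.83, SE 0.12, to -0.78, SE 0.14) no longer passed. Their changes moved little and their standard errors were larger. A lower share of blood in the failure samples cannot be told apart: 3 neutrophil and platelet markers above the array median had a median change of -0.0857 (SE 0.0508), but 0 of 11 lay at least 2-fold above it. Lymphocyte markers lay lower in 7 of 10, which goes with this explanation in direction, but their median was -0.0756 against -0.83 for the red blood cell genes. CD8A (-0.49) and KLRK1 (-0.36) were each lower in 8 of 9 pigs. In contrast, CD8B (0.00498), CD79B (0.00125) and CCR7 (0.0161) were not lower. All 10 lay below the array median of 5.63, with CD8A at 4.72, KLRK1 at 4.08 and the brightest, CD8B, at 5.20. The level bound for neutrophil and platelet markers was raised after the first result, which had counted against this explanation, was seen. HBB had the same mean level as ALAS2 (7.94) but changed by -0.24 against -1.27. An equal loss of all red blood cell transcripts would not give this difference alone, but it rests on 1 gene and does not decide the question. Time under anaesthesia and surgery cannot be told apart from ischemia, since 0 of the arrays are time-matched samples without ischemia, and an effect of failure itself stays open.

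One B2M probe set fell by 1.28 and 8 others did not. If the probe table assigns these 8 rightly, their median of -0.0454 (SD 0.112) argues against a fall of the B2M transcript. Probe sequences were not checked, and the mean levels of the 9 ran from 5.74 to 13.20. That the falling probe set follows red blood cell transcripts stays open. Its change correlated with the mean change of ALAS2, AHSP and HBM with r = 0.619 (exact permutation p = 0.0758, adjusted 0.153 over 6 relations) and rho = 0.433 (exact permutation p = 0.2499). Without pigs 8 and 14 r was 0.558, and within label set 1 it was -0.14 (6 pigs; label set 2 has too few). No biological explanation was tested.

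Inflammatory genes varied together between pigs: the estimated correlation between the 18 members was 0.657, and 0 of 1000 random lists matched on level reached it (95th percentile 0.0756). These lists were not matched on the spread between pigs, which was 2.15 (SD) for the IL6 change against a median of 0.216 over all probe sets. The share of 0 in 1000 may therefore overstate how unusual the joint variation is. RNA degradation is argued against as the whole source, since the estimated correlation was 0.661 with the covariate. A difference between label sets is argued against as well, since it was 0.559 within label set 1 alone (95th percentile of random lists 0.0895). A difference between animals in their response stays open, as a hypothesis that was not tested.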

How the results depend on the processing

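The rounding, the covariate for RNA quality and the lists of at least 3 members were chosen after the data had been seen. Array median centring and quantile normalization each kept all 16 probe sets. The distributions were near-identical beforehand, so these scalings could change little. Rounding kept them too, but all 16 already had at most 2 decimals, so their own values could not move. Direction was the same for the 7 called genes under all 15 alternatives run on each. These genes had been chosen for a shared direction across pigs, so the fits on fewer pigs could hardly reverse it. The fit with no replicate block gives the same mean change by construction. In those fits the shared direction is therefore no separate evidence. The cause of the changes below was not tested, except that fewer pigs or genes entered some fits.

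For the paired count of 16 (5 higher, 11 lower, 5 at least 2-fold), the fit with no replicate block gave 0, 0, 0 and 0. The unmoderated paired test and label set 2 alone also gave 0 in each. Label set 1 alone gave 3 (0 higher, 3 lower, 3 at least 2-fold). Pig as a random effect gave 15, of which 8 were higher and 7 lower, and 9 were among the 16. Leaving out the dimmest 50% gave 9 (0 higher, 3 at least 2-fold), 1 probe set per gene gave 7 (2 higher, 5 lower, 3 at least 2-fold), and the trend with robust prior gave 10 (6 lower, 1 at least 2-fold). The covariate gave 9 (2 higher, 7 lower, 2 at least 2-fold), 8 among the 16. With each pig left out in turn the counts ran from 2 to 26, 0 to 11 higher, 2 to 15 lower and 1 to 7 at least 2-fold. Array weights (19) and the dimmest 25% left out (15) stayed within 1.5 times.

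The 9 gene lists became 2 with no replicate block, 0 with an estimated correlation and 3 with the covariate, and ran from 4 to 14 with each pig left out. The mean of oxidative phosphorylation went from -0.0514 to about 0 with the covariate (0.000140, adjusted p = 0.893). With lists of at least 3 members, red blood cell markers passed (adjusted p = 3.22e-11; 0.0241 with an estimated correlation). The interaction count was 0 under every alternative run, with 1045 to 1782 at an unadjusted p under 0.05 over all tested probe sets. With the dimmest 25% left out, where fewer probe sets were tested and fewer are expected by chance, there were 1008.

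Of 100 splits that part every pair (256 are possible), 1 gave 16 or more probe sets, the real one, and the highest other gave 1. A share of 1 in 100 is the smallest that this draw can give. It makes chance an unlikely source of that count but does not exclude it. Of 100 splits into 9 and 9, 2 did, and the highest other gave 24. The others parted 1 to 7 pairs, so in this fit they rest on the differences of fewer pigs. For the gene lists, 14 of 100 pair-parting splits gave 9 or more (highest other 14), so chance is not excluded. For label sets the real count is 0, which all 84 splits reach by construction, so the splits say nothing about chance (set as undecided after the count was seen); the highest other gave 16.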

Other observations

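Members of several lists departed from their mean changes together, pig by pig. Random lists were matched on level, not on the spread between pigs. The estimated correlation between members was above the 95th percentile of 200 such lists in 16 of 32 lists. It was 0.593 for interferon-stimulated genes, 0.484 for monocyte and macrophage markers, 0.423 for oxidative phosphorylation and 0.414 for immediate early genes. Hypoxia targets (0.00292), lymphocyte markers (-0.01) and neutrophil markers (-0.03) did not exceed it.

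The tests in the next paragraphs were chosen after the values were seen.

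IL6 and NPPB may have moved in opposite directions across pigs (r = -0.73, exact permutation p = 0.0263, adjusted 0.153 over 6 relations; rho = -0.62, exact permutation p = 0.0857). Without pigs 5 and 8 r was -0.05, so the relation rests on those pigs, and within label set 1 it was -0.49 (6 pigs; label set 2 has too few). NPPA and NPPB had r = -0.61 (exact permutation p = 0.0767, adjusted 0.153) and rho = -0.77 (exact permutation p = 0.0214), with r = -0.78 without pigs 9 and 12 and -0.57 within label set 1. Neither relation passes the adjustment.

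The number of decimals may mark probe sets past an unadjusted paired test in an earlier processing step. Of the 1473 probe sets with at most 2 decimals, 97.6% (1437) had an unadjusted paired p under 0.05, computed from the 9 differences, against 0 of the other 22650, whose lowest was 0.05001. The remaining 36 had values up to 0.0564. Rounding 1294 other probe sets with values under 0.1 to 2 decimals moved them by up to 0.0167. The counts of called probe sets were the same with all values rounded (16). All 16 already had at most 2 decimals, so rounding could not move their own values.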
